A study of Mus musculus with 30 samples.

How the data were processed

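Gene expression was measured in CD4 T cells sorted from the spleens of C57BL/6 mice 8 weeks old, in 30 libraries. Per the labels, RNA was extracted with Trizol from sorted cells and 10 ng of total RNA entered each library. The NEB Next Ultra kit made 8 RNA-seq libraries and the Lexogen QuantSeq kit, which reads the 3' ends of transcripts, made 22. The series description names the Illumina HiSeq1500. Samples were grouped by the kit, genotype and sort gate in their labels, which gave 14 groups of 1 to 4 libraries. The labels name no animal, replicate number or batch, so no library was paired with another and no covariate entered any model.

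The submitters' processing notes list Bowtie 0.12.2, STAR 2.7.0c and featureCounts 1.6.0 and the genome builds mm10, GRCm38.p6 and mm9. Which program and build made which file is not given in the sources used here. The deposited QuantSeq values are whole counts per gene. The deposited RNA-seq values are whole counts per transcript. The design written before the data were examined allowed for a length-scaled unit in the RNA-seq files. Because those files hold counts, its rule for counts was followed. Gene names came from GENCODE M21, built on GRCm38. Of 55573 QuantSeq gene identifiers, 93 had no name there and held 0.0062% of counts. Of 95883 RNA-seq transcript identifiers, 82946 were named, and the others held 14.66% of counts and were left out. The named transcripts belong to 34030 genes, 12347 of them with several transcripts. Sums over transcripts were 2.517 times the counts of the most abundant transcripts, and whether a read was counted on several transcripts of a gene is not given in the sources used here. Each gene was therefore represented by its transcript with the highest total count, and depths below are sums of transcript counts.

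QuantSeq and RNA-seq libraries were never put in the same fit. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15), a robust quasi-likelihood fit and its 2-sided test. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and an adjusted p under 0.05 is a call. The QuantSeq fit held 14383 genes, 9 groups and 13 residual degrees of freedom. The RNA-seq fit held 17013 genes, 5 groups and 3 residual degrees of freedom. Normalization factors ranged from 0.93 to 1.08 and from 0.96 to 1.06. In all, 12 comparisons were tested. Levels are given as mean counts per M counts (CPM, M being 10 to the power 6) ± standard deviation over libraries, and differences as log2 ratios ± standard error. Where 1 group had no count, a fold is given as a bound, with 3 counts put in each empty library. Where a group held 1 to 4 counts in total, its count is given and no fold. Standard errors of single genes come from the fit, and bounds cover counting error only. P values measure the spread between these libraries, which may be technical replicates or separate mice.

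In QuantSeq, a library held 1.83 to 4.44 M counts (median 2.95) and 7456 to 10585 genes with at least 10 counts. The biological coefficient of variation of the fit was 1.26. Over 18 pairs of replicates the chi-square per degree of freedom was 35.1 to 56.1, and 22.76 to 31.19% of genes above 200 counts differed more than 2-fold. In RNA-seq, a library held 36.05 to 107.4 M counts (median 67.62) and 13029 to 15197 genes with at least 10 counts. There the coefficient was 0.0879, the chi-square per degree of freedom 2.65, 5.31 and 21.4 over 3 pairs, and 0.68 to 1.71% of genes differed more than 2-fold. RNA-seq replicates are thus close to technical repeats, and their p values say little about other mice. Changes of known size were added to these counts, and recovery was tested on simulated data. At 4-fold, 36% of changes were recovered between TFH2 and TFH, 21.5% between CXCR5 gates, 13.5% between TFH CXCR5hi and TH2, 6% between Bcl6KO and TH2, and 97.5% between RNA-seq TFH and TH2.

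The following 19 gene lists were fixed before the data were examined: TFH, TH2, TH1 and cytotoxic, TH17, regulatory T cell, naive and recirculating, cell cycle, immediate early, inhibitory receptor, interferon response, cholesterol synthesis, glycolysis and hypoxia, nuclear-encoded respiratory chain, ribosomal protein, mitochondrially encoded, B cell, myeloid, CD8 and NK cell, and erythroid. Pdcd1 and Btla stand in the TFH and inhibitory receptor lists, Tigit and Ctla4 in the regulatory and inhibitory receptor lists, and Fcgr3 in the myeloid and NK cell lists. Lists were tested with camera in limma 3.58.1 at a correlation of 0.01 between genes, with adjustment over the 19 lists. The same test with a correlation estimated per list, and fry, were the alternatives. List counts come from the gene test over all genes and again with adjustment over the list alone. List medians of log2 ratios are given with genes of an empty group at their bound in brackets where the 2 values differ.

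Genes to name were chosen by a rule written before the data were examined. From each list it takes up to 4 called genes with the smallest adjusted p, or else the 2 most expressed. It adds the 8 highest and 8 lowest log2 ratios among called genes with a mean of at least 5 CPM whose groups do not overlap, without predicted genes or receptor segments. Bcl6, Il4, Cxcr5, Pdcd1, Gata3, Il21, Il13 and Il5 are always reported. From this set the report mainly describes genes whose call held with every library left out in turn. The share that held is given in each comparison. Results for 2 genes that the rule selects are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

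Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a fit on only the groups compared, each library left out, an adjusted p under 0.01, and subsets of the TH2 libraries. For RNA-seq they were limma on log2 CPM with 0.1 or 5 added, no filter, the 6 libraries of replicated groups alone, and the library labelled TH2 of the IL-4BacTg x OTII mice put in the TH2 group. Chosen after the data were seen were a fit without the 3 QuantSeq libraries of lowest depth, and for RNA-seq DESeq2, RLE factors, summed transcripts and a test against a 2-fold change. Principal components used the 2000 most variable genes and log2 CPM with a prior count of 2. The 2 RNA-seq groups with 1 library each were not tested, and their list medians were set against 10000 random lists of similar expression. Reads were not analysed here.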

Results

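T helper cells from mouse spleen were profiled in 30 libraries. QuantSeq covered TH2 cells (n = 4), TFH cells of OTII mice sorted through CXCR5hi (n = 3), CXCR5int (n = 2) and CXCR5lo (n = 3) gates, and TFH2 cells, the labels' name for cells of IL-4BacTg x OTII mice in the same 3 gates (n = 2 each). It also covered Bcl6KO (n = 2) and Il4-/- (Il4KO, n = 2) cells. TH2 and Bcl6KO cells were sorted as CD4+hCD2+ and Il4KO cells as CD4+. TFH and TFH2 cells were sorted as CD4+CD45.2+ PD1+ at the CXCR5 level named. By their labels, QuantSeq TH2 cells were IL-4BacTg x OTII, Bcl6KO cells Bcl6f/fCd4cre x OTII and Il4KO cells Il4-/- x OTII. RNA-seq covered naive CD4 cells of wild type mice (n = 2), TH2 cells of IL-4BacTg mice (n = 2) and TFH CXCR5hi cells of OTII mice (n = 2). It also held 1 library each labelled TH2 and TFH2 CXCR5hi from IL-4BacTg x OTII mice. Comparisons among naive, TH2 and TFH groups therefore differ in genotype and gate beside cell type.

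QuantSeq depth, in M counts (10 to the power 6), was 2.56, 2.96, 3.02 and 1.85 for TH2, 2.48 and 2.73 for TFH2 CXCR5hi, 2.47 and 4.44 for TFH2 CXCR5int, and 2.84 and 1.83 for TFH2 CXCR5lo. It was 2.93, 2.94 and 4.03 for TFH CXCR5hi, 4.05 and 2.41 for CXCR5int, 3.65, 4.37 and 3.07 for CXCR5lo, 3.12 and 2.05 for Bcl6KO, and 3.48 and 3.06 for Il4KO. RNA-seq depth was 96.0 and 107.4 for naive, 63.32 and 71.92 for TH2, 82.7 and 57.57 for TFH, 41.75 for the library labelled TH2 of the IL-4BacTg x OTII mice and 36.05 for the library labelled TFH2.

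Bcl6, the repressor that directs TFH fate and the gene targeted in Bcl6KO mice, had 21 and 54 counts in the Bcl6KO libraries (6.77 and 25.6 CPM). TH2 libraries held 1, 39, 6 and 11 Bcl6 counts (0.392, 13.3, 2.05 and 5.96 CPM) and Il4KO libraries 46 and 30 (14.2 and 10.3 CPM). The tables do not show which part of Bcl6 these tags come from. Il4 had 0 and 3 counts in the Il4KO libraries and 0 in both Bcl6KO libraries. Of the TH2 libraries only replicate 3 held Il4, with 40 counts (13.7 CPM). TFH2 CXCR5hi libraries held 48.9 ± 9.89 CPM of Il4.

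Sex-linked transcripts part the groups. Ddx3y, a Y-linked RNA helicase, was at 48.8 to 98.9 CPM in all 6 TFH2 libraries and had 0 counts in all 8 TFH libraries, where Xist was at 174 to 538 CPM. In TFH2 libraries Xist was at 0 and 0.407 CPM in the CXCR5hi gate and 8.79 to 20.9 CPM in the other gates, and whether a share of female cells differs by gate was not tested. TH2 replicates 1 and 2 held Xist (339 and 383 CPM) and replicates 3 and 4 held Ddx3y (100.5 and 28.7 CPM). Bcl6KO libraries held Xist (219 and 221 CPM) and Il4KO libraries Ddx3y (82.8 and 72.4 CPM). Donor sex therefore follows genotype in each comparison of TFH2 with TFH and of Bcl6KO with Il4KO. In RNA-seq, the TFH libraries held Ddx3y (82.5 and 85.2 CPM) with Xist under 1 CPM, while naive and TH2 libraries held Xist (577 to 1247 CPM) with Ddx3y under 1 CPM. Donor sex thus follows cell type in both RNA-seq comparisons of TFH cells, where Ddx3y is among the called genes (4 counts in naive and 1 in TH2 libraries, adjusted p 1.42e-11 and 1.02e-11).

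Principal component 1 of QuantSeq held 20.4% of the variance and placed TH2, Bcl6KO and Il4KO libraries at -67.46 to -50.04 and all TFH and TFH2 libraries at 19.98 to 48.26. Component 2 held 6.8%. Ribosomal protein transcripts were 17.4 to 19.0% of counts in TH2, Bcl6KO and Il4KO libraries and 9.28 to 12.9% in TFH and TFH2 libraries.

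**Figure D1:**
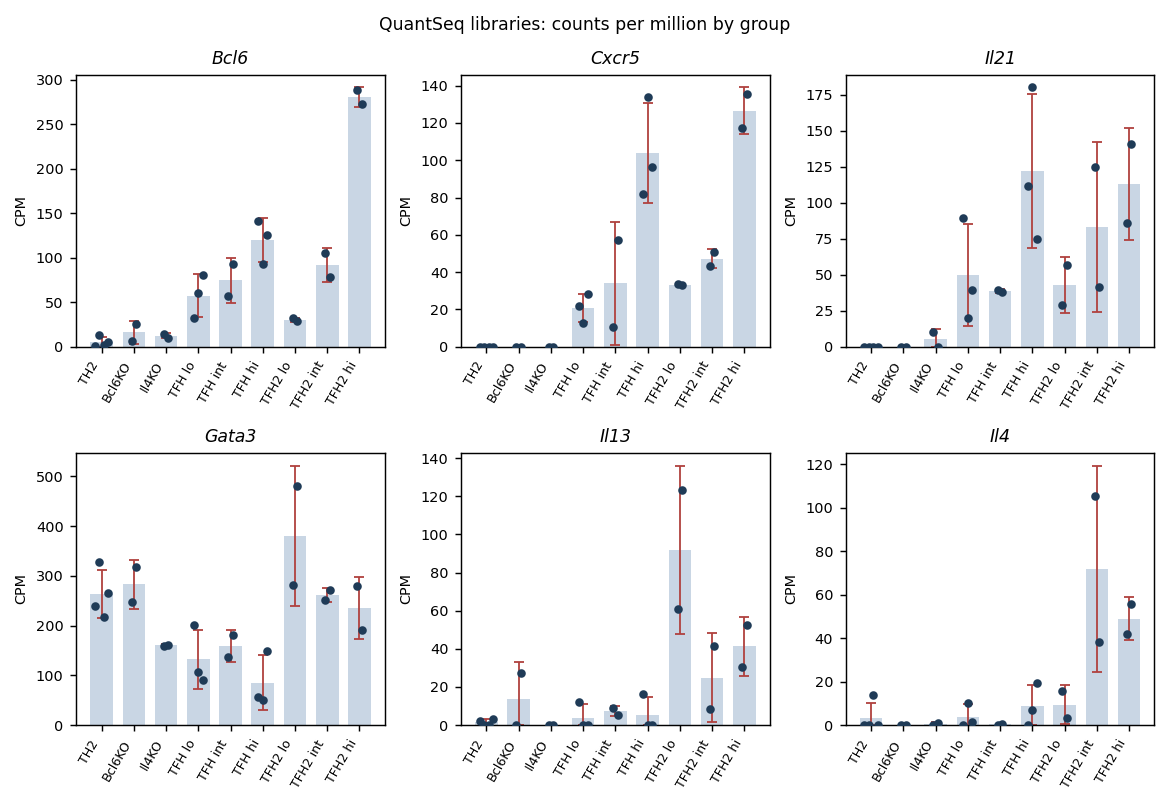
Expression of Bcl6, Cxcr5, Il21, Gata3, Il13 and Il4 in the 9 QuantSeq groups. Bars are means, points are libraries and red lines are standard deviations.

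TFH CXCR5hi cells (n = 3) carried the transcripts of B cell help that TH2 cells (n = 4) lacked. Il21, the cytokine that sustains germinal centre B cells, stood at 122 ± 53.5 CPM and had 0 counts in TH2 libraries (at least 101-fold, adjusted p 2.32e-11). Bcl6 was 4.46 ± 0.67 log2 higher (120.2 ± 24.6 against 5.42 ± 5.74 CPM, adjusted p 2.38e-07). Tox2, a nuclear factor of TFH cells, stood at 917 ± 210 CPM against 2 counts in all TH2 libraries (adjusted p 3.5e-12). Pdcd1, which encodes the PD1 receptor of the gate, stood at 189 ± 33.3 CPM against 3 counts (adjusted p 2.41e-05), and Cxcr5, also part of the gate, at 104 ± 26.8 CPM against 0 (at least 85.8-fold, adjusted p 1.39e-09).

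Other genes found in TFH CXCR5hi cells and not in TH2 cells were Cebpa, a transcription factor better known from myeloid cells (92.9 ± 7.63 CPM against 0, at least 76.7-fold, adjusted p 2.57e-07), and Nav2, a cytoskeletal guidance factor (66.3 ± 28.2 CPM against 0, at least 54.7-fold, adjusted p 2.05e-11). Angptl2, a secreted TFH product, stood at 104 ± 59.3 CPM against 2 counts (adjusted p 4.56e-08). Of the inhibitory receptors, Cd160 stood at 147 ± 81.5 CPM against 2 counts (adjusted p 8.85e-17). Activation genes were higher: Nr4a3, induced by the T cell receptor, by 7.32 ± 0.87 log2, Dusp1, a MAP kinase phosphatase, by 3.2 ± 0.48, Nfkbia, the NF-kB inhibitor, by 1.97 ± 0.17, and Junb, an AP-1 subunit, by 1.71 ± 0.16 (adjusted p 4.25e-11, 0.000441, 1.76e-18 and 3.56e-16). So were interferon genes. Oas1g, an antiviral synthetase, stood at 104.5 ± 64.4 CPM against 0 (at least 86.2-fold), and Ifit3 was 6.36 ± 1.11, Isg20 2.45 ± 0.35 and Zbp1 1.90 ± 0.41 log2 higher (adjusted p 1.01e-07, 0.000313, 4.63e-08 and 0.000887).

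Several single genes were higher in TH2 cells. Il4ra, the IL-4 receptor, was at 1786 ± 342 CPM in TH2 cells and 123 ± 72.4 in TFH CXCR5hi cells (log2 -3.86 ± 0.49, adjusted p 0.000124). Gata3, the master factor of TH2 cells, was at 263 ± 48.0 against 85.6 ± 54.4 CPM (log2 -1.62 ± 0.36, adjusted p 0.00157), and its call was lost without TFH CXCR5hi replicate 2 (adjusted p 0.0553). S1pr1, the receptor for exit into blood, was lower in TFH CXCR5hi cells by log2 -3.57 ± 0.45, and Satb1, a chromatin organizer of resting T cells, by -3.07 ± 0.30 (adjusted p 5.85e-10 and 2.09e-15). Cxcr6, a homing receptor, was lower by -2.49 ± 0.50 and Runx3, a cytotoxic lineage factor, by -2.07 ± 0.43 (adjusted p 0.000232 and 0.000412). Vipr1, a neuropeptide receptor, Mgll, a lipase, and Ly6c2, a memory marker, had 0 counts in TFH CXCR5hi cells against 61.9 ± 23.7, 58.5 ± 41.9 and 45 ± 43.5 CPM (at least 66.2-, 62.6- and 48.2-fold lower, adjusted p 0.00113, 0.000448 and 0.0028). Bach2, a repressor of effector genes, stood at 2 counts against 75.5 ± 35.3 CPM (adjusted p 3.01e-05). Rps3, a ribosomal protein, was lower by -1.26 ± 0.19 (adjusted p 1.67e-07). Il4 (8.78 ± 9.76 against 3.42 ± 6.84 CPM) and Il13 (5.45 ± 9.44 against 1.4 ± 1.66 CPM), the TH2 cytokines, did not pass (adjusted p 0.856 and 0.679), and Il5 had 0 counts in both.

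Between TFH CXCR5hi and TH2, edgeR called 505 genes, 295 higher and 210 lower (482 and 495 with DESeq2, 207 and 208 in a fit on only these groups), and in 469 of them the groups did not overlap, as in 12.16% of all genes tested. Without TFH CXCR5hi replicate 2 the count was 336. Of 53 called genes under the naming rule, 38 held their call with every library left out. By list, 14 of 20 TFH genes were higher and 0 lower (19 and 0 over the list alone, median log2 4.07 [3.85], camera adjusted p 2.28e-32), as were 7 of 20 interferon response genes (13 and 0, median 2.51, 1.5e-15), 6 of 19 immediate early genes (11 and 1, median 1.95, 4.55e-09) and 3 of 9 inhibitory receptor genes (4 and 1, median 4.21 [3.75], 6.51e-05). Lower were 12 of 18 ribosomal protein genes (14 over the list alone, median -0.94, 1.11e-08), 4 of 19 naive and recirculating genes with 1 higher (9 and 3, median -3.07 [-0.65], 1.28e-06) and 4 of 18 TH1 and cytotoxic genes (6 and 0, median -2.97 [-2.02], 3.93e-05). The TH2 list did not pass (3 of 16 lower, 3 and 2 over the list alone, adjusted p 0.244). With an estimated correlation these 7 calls held, also with every library left out.

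Some markers of B cells, macrophages and red cells were higher in TFH CXCR5hi than in TH2 libraries. Igkc, the antibody light chain of B cells, stood at 41.4 ± 18.5 CPM against 3 counts, and Hbb-bs, an adult globin that shares reads with its paralog, at 56 ± 9.93 CPM against 2 counts (adjusted p 5.83e-11 and 1.2e-08). Csf1r, the macrophage growth factor receptor, stood at 32.8 ± 8.71 CPM against 2 counts (adjusted p 1.07e-09), a call lost in a fit on only these groups (adjusted p 0.0515, range over alternatives 1.93e-12 to 0.0515). The myeloid list was higher (2 of 12 genes, 4 over the list alone, median 4.89 [1.29], camera adjusted p 0.00462, with an estimated correlation 0.0254), but not without TFH CXCR5hi replicate 2 (0.0574 with an estimated correlation). Camera also called the B cell list (1 of 14, 2 over the list alone, median 1.76 [0.42], adjusted p 0.00866) and the erythroid list (2 of 5, 2 over the list alone, median 2.32, 0.00141). With an estimated correlation neither passed (adjusted p 0.0982 and 0.0515).

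TFH2 CXCR5hi cells (n = 2) differed from TH2 cells (n = 4) in the same TFH genes. Il21 stood at 113 ± 38.7 CPM against 0 (at least 93.4-fold, adjusted p 6.58e-11), Cxcr5 at 126 ± 12.5 CPM against 0 (at least 104-fold, adjusted p 1.36e-09), and Bcl6 was 5.68 ± 0.73 log2 higher (280.5 ± 11.1 CPM, adjusted p 1.19e-09). Tox2 stood at 855 ± 18.5 CPM against 2 counts, Nav2 at 190.5 ± 51.0 CPM against 0 (at least 157-fold), Cd160 at 219 ± 42.2 CPM against 2 counts and Pdcd1 at 185 ± 29.6 CPM against 3 counts (adjusted p 5.11e-12, 1.66e-13, 1.7e-17 and 3.91e-05). Gata3 was at 236 ± 63.2 CPM in TFH2 CXCR5hi and 263 ± 48.0 in TH2 cells and did not pass (adjusted p 0.991). Il4 and Il13 also did not pass (48.9 ± 9.89 against 3.42 ± 6.84 and 41.4 ± 15.4 against 1.4 ± 1.66 CPM, adjusted p 0.422 and 0.248), nor did Il5, with 0 counts in both.

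Lower in TFH2 CXCR5hi than in TH2 cells were Il4ra (log2 -4.57 ± 0.62, adjusted p 0.000244), Runx3 (-4.04 ± 0.57, 3.55e-08), Satb1 (-3.29 ± 0.36, 9.68e-13) and S1pr1 (-2.88 ± 0.52, 2.63e-05). Bach2 had 0 counts against 75.5 ± 35.3 CPM (at least 66-fold lower, adjusted p 0.000284), Arid3b, a DNA-binding cofactor, 0 against 101 ± 70.5 (at least 88.4-fold, 0.00772), Ecm1, a TH2 egress factor, 0 against 144 ± 129 (at least 126-fold, 0.0316) and Il18r1, the IL-18 receptor, 0 against 62.5 ± 31.3 (at least 54.6-fold, 0.0177). Activation genes were higher, with Nr4a3 at 6.78 ± 0.87, Dusp1 at 3.65 ± 0.51, Nfkbia at 2.44 ± 0.18 and Junb at 1.44 ± 0.18 log2 (adjusted p 1.37e-09, 0.000244, 1.81e-22 and 1.47e-10). Isg20 was higher by 1.95 ± 0.38 (adjusted p 0.000135), and 2 mitochondrial genes of the respiratory chain, mt-Nd4 and mt-Cytb, by 0.91 ± 0.18 and 0.79 ± 0.16 (adjusted p 0.000942 and 0.000331). Rps3 was lower by -1.58 ± 0.22 (adjusted p 3.55e-08).

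Markers of the same 3 cell types were also high in these libraries. Hbb-bs stood at 577 ± 69.9 CPM against 2 counts, Igkc at 451 ± 210 CPM against 3 counts and Csf1r at 328 ± 103 CPM against 2 counts (adjusted p 9.88e-12, 4.35e-17 and 1.13e-15). Slpi, a protease inhibitor of myeloid and epithelial cells, stood at 98.5 ± 21.3 CPM against 0 (at least 81.2-fold, adjusted p 0.000852). H2-Aa, an MHC class II chain, stood at 78.5 ± 10.3 CPM against 0 (at least 64.8-fold, adjusted p 0.000813), but DESeq2 did not call it (adjusted p 0.0627, range over alternatives 7.75e-06 to 0.0627). The myeloid list was higher in 4 of 12 genes (9 over the list alone, median 8.44 [3.62], camera adjusted p 8.92e-11), the erythroid list in 2 of 5 (5 over the list alone, 7.06 [5.67], 1.82e-08) and the B cell list in 3 of 14 (6 over the list alone, 5.06 [2.66], 2.69e-07).

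For TFH2 CXCR5hi against TH2, edgeR called 423 genes, 244 higher and 179 lower. The balance turned with DESeq2 (379 and 448) and in a fit on only these groups (168 and 217). In 417 of them the groups did not overlap, as in 19.15% of all genes tested. Of 47 called genes under the naming rule, 33 held with every library left out. The TFH list was higher in 12 of 20 genes (20 over the list alone, median 4.46, camera adjusted p 2.34e-28), the immediate early list in 5 of 19 (10, median 2.02 [1.93], 8.93e-07) and the inhibitory receptor list in 3 of 9 (4, median 4.80 [4.58], 2.87e-05). The ribosomal protein list was lower in 12 of 18 (13, median -1.02, 8.99e-10) and the naive and recirculating list in 5 of 19, with 1 higher (8 and 2, median -2.23, 2.69e-07). These 5 lists and the myeloid, erythroid and B cell lists held with an estimated correlation and with every library left out. The TH1 and cytotoxic list (3 of 18 lower, 3 over the list alone, median -0.71, camera adjusted p 0.00357) and the interferon response list (2 of 20 higher, 2 over the list alone, median 1.15, 0.00357) were lost with an estimated correlation (adjusted p 0.0849 and 0.0566). The TH2 list did not pass (1 of 16 higher and 2 lower, 4 and 3 over the list alone, adjusted p 0.886). In 3 lists that did not pass, median and test differ in sign: TH17 (median -0.85, test up, 0.507), regulatory T cell (0.22 [-0.07], test down, 0.326) and cholesterol synthesis (-0.2, test up, 0.886).

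TFH2 cells (n = 6 over 3 gates) differed from TFH cells (n = 8) in the TH2 and interferon lists, though few single genes of either passed. Gata3 was 1.23 ± 0.25 log2 higher in TFH2 cells (292.8 ± 97.9 against 125.8 ± 55.0 CPM, adjusted p 0.00107). Cxcr6, of the TH1 and cytotoxic list, was 2.65 ± 0.34 higher (127 ± 86.7 against 19.7 ± 10.4 CPM, adjusted p 2.62e-08). Irf7, the factor that amplifies type I interferon, was lower (25.8 ± 17.1 against 146 ± 27.0 CPM, log2 -2.70 ± 0.50, adjusted p 0.000243). The genes that the gates select did not part these cells: Cxcr5 (69.0 ± 45.3 against 53.0 ± 45.0 CPM) and Pdcd1 (111 ± 72.9 against 103 ± 73.9 CPM) stood at adjusted p 1, as did Bcl6 (134 ± 117 against 84.2 ± 36.2 CPM) and Il21 (79.7 ± 45.4 against 70.2 ± 52.7 CPM).

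Il4 was at 43.4 ± 35.9 CPM in TFH2 and 4.33 ± 7.01 in TFH libraries and Il13 at 52.8 ± 39.0 and 5.54 ± 6.46 CPM, yet neither passed (log2 3.78 ± 1.42 and 3.08 ± 1.27, adjusted p 0.292 and 0.377). Il5, the eosinophil cytokine, was at 16.6 ± 26.4 CPM against 0. Its test cannot decide, since the contrast takes in empty groups and the log2 ratio has a standard error of 13678. By gate, mean Il4 in TFH2 libraries was 48.9, 72.2 and 9.43 CPM from hi to lo, Il13 41.4, 24.9 and 91.9, and Il5 0, 4.06 and 45.8. Lower in TFH2 cells were genes of quiescence and recirculation: Klf2, which drives S1pr1 (log2 -1.44 ± 0.25, adjusted p 9.93e-05), Foxp1 (-1.02 ± 0.22, 0.00321) and Actn1, an actin crosslinker (-1.61 ± 0.24, 1.51e-06). Socs3, a brake on cytokine signals, was lower by -1.29 ± 0.23 (adjusted p 0.00013), and the mitochondrial ribosomal RNA mt-Rnr2 by -0.55 ± 0.10 (adjusted p 0.000809). Interferon genes whose call was lost without some library were Ifi27l2a (log2 -2.03 ± 0.36, adjusted p 0.0187) and Ifit3 (-3.03 ± 0.72, 0.04). Ifi27l2a was lost without either CXCR5hi or CXCR5int TFH2 library or TFH2 CXCR5lo replicate 2 (0.055 to 0.0857), and Ifit3 without TFH CXCR5hi replicate 2 (0.0565) or TFH CXCR5lo replicate 3 (0.0618).

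Myeloid, B cell and erythroid transcripts were higher in the same TFH2 libraries. Epas1, a hypoxia factor, was 3.32 ± 0.64 log2 higher (adjusted p 0.00107). C1qc, the complement chain of macrophages, was 2.73 ± 0.52 higher (173 ± 92.2 against 26.4 ± 15.2 CPM), Csf1r 2.62 ± 0.48 (193 ± 137 against 27.2 ± 10.9 CPM) and Igkc 2.41 ± 0.40 (263 ± 206 against 43.9 ± 16.6 CPM; adjusted p 0.000427, 0.000213 and 8.78e-05). H2-Aa was 6.32 ± 1.28 higher (adjusted p 0.00321), a call DESeq2 does not make (0.112, range over alternatives 1.3e-05 to 0.112). Hbb-bs was 2.69 ± 0.41 higher (370.4 ± 201 against 54.9 ± 39.2 CPM, adjusted p 0.00013), not so in a fit on only these groups (0.0672, range over alternatives 5.68e-14 to 0.0672). By gate, TFH2 means from hi to lo were 328, 176 and 75.2 CPM for Csf1r, 451, 139 and 198 for Igkc, and 578, 323 and 210 for Hbb-bs. TFH means were 18.9 to 32.8, 41.4 to 48.4 and 35.9 to 72.9 CPM.

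Over the 3 gates, edgeR called 93 genes between TFH2 and TFH, 47 higher and 46 lower (56 and 34 with RLE factors, 134 and 145 with DESeq2, 65 and 74 in a fit on only these groups), and 1385 had an unadjusted p under 0.05. The labels do not say whether the 3 gates share mice, and if they do these p values are too small. In 28 calls the groups did not overlap, as in 0.49% of all genes tested. Without TFH2 CXCR5lo replicate 1 the count was 214, 74 higher and 140 lower. That library held 0 counts of Pdcd1, though PD1 is part of its gate. Of 25 called genes under the naming rule, 15 held with every library left out. They include the sex-linked Ddx3y (71.5 ± 20.4 CPM against 0, at least 78.2-fold, adjusted p 3.4e-06).

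By list, the interferon response was lower in 4 of 20 genes (17 over the list alone, median log2 -1.95, camera adjusted p 1.21e-20) and the naive and recirculating list in 4 of 19 (6 lower and 1 higher over the list alone, median -0.60, 0.000159). The TH2 list was higher in 1 of 16 genes (6 over the list alone, median 1.99, 4.71e-08), the myeloid list in 1 of 12 (2, median 2.54, 4.17e-10) and the erythroid list in 1 of 5 (5, median 3.34 [2.69], 7.16e-09). These 5 held with an estimated correlation and with every library left out. The TH1 and cytotoxic list was higher (1 of 18, 5 higher and 1 lower over the list alone, median 2.13 [1.86], 4.33e-05, with an estimated correlation 0.025). It was lost without TFH2 CXCR5lo replicate 1 (0.0903), TFH2 CXCR5hi replicate 2 (0.0606) or TFH CXCR5int replicate 2 (0.0531). The B cell list was higher (2 of 14, 5 over the list alone, median 1.41, 0.000159, with an estimated correlation 0.0257). It was lost without any 1 TFH2 library or TFH CXCR5int replicate 1 or 2 (0.0561 to 0.257). The TFH list did not pass (1 of 20 lower, 1 higher and 1 lower over the list alone, median -0.09, adjusted p 0.276), and the other lists stood at adjusted p 0.0688 to 0.89.

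**Figure D2:**
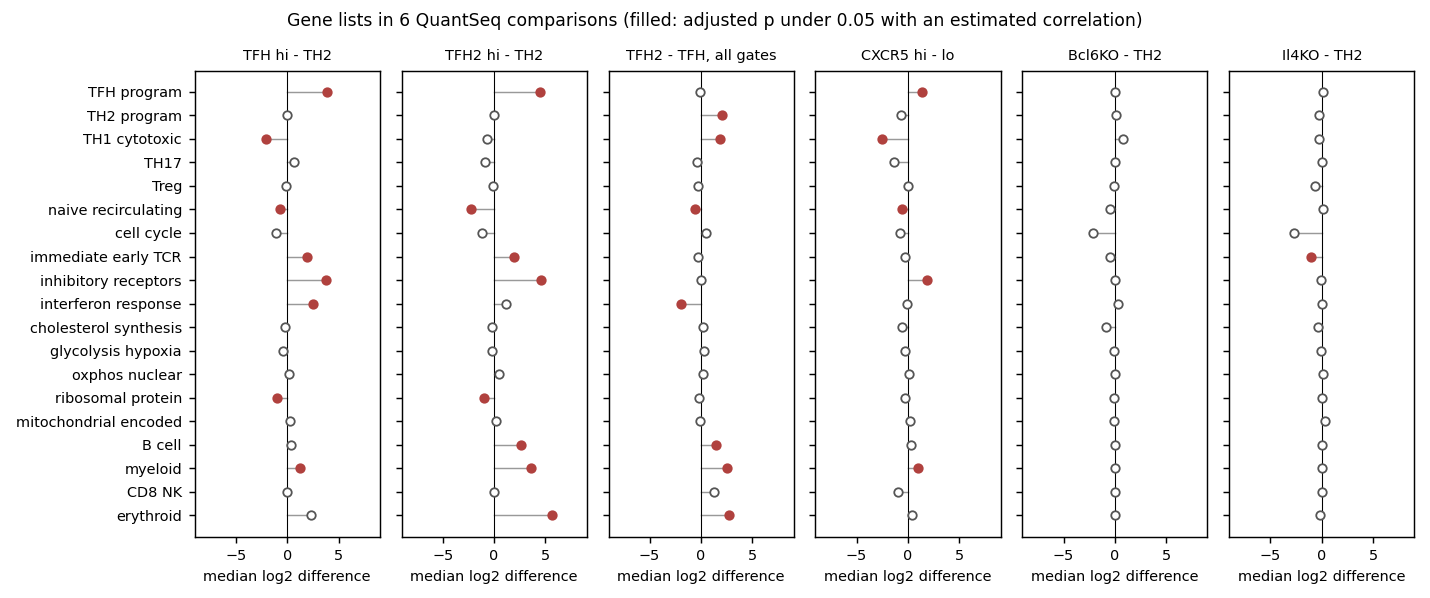
Median log2 difference of 19 gene lists in 6 QuantSeq comparisons, with genes of an empty group at their bound. Filled points have an adjusted p under 0.05 with an estimated correlation.

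Within the CXCR5hi gate alone, TFH2 (n = 2) and TFH (n = 3) cells differed in few single genes. Klf2 was lower in TFH2 cells (34.8 ± 12.9 against 157 ± 26.9 CPM, log2 -2.17 ± 0.44, adjusted p 0.0209). Igkc was 3.44 ± 0.67 and Hbb-bs 3.36 ± 0.67 log2 higher (adjusted p 0.0209 and 0.0433), C1qc 4.07 ± 0.87 (0.0335), Ifngr1, the interferon gamma receptor, 3.16 ± 0.71 (38.1 ± 23.7 against 4.16 ± 3.45 CPM, 0.0438) and Psap, a lysosomal activator, 1.22 ± 0.27 (2112 ± 395 against 910 ± 313 CPM, 0.0438). Pik3r5, a PI3 kinase subunit, stood at 13.2 CPM against 1 count. Chuk, an NF-kB kinase, stood at 1 count against 44.4 CPM and Hist1h1e, a linker histone, at 1 count against 30.6 CPM (adjusted p 0.0438, 0.0495 and 0.0438). The last is Ddx3y (64.4 CPM against 0, at least 69-fold, 0.0335). Bcl6 (280.5 ± 11.1 against 120.2 ± 24.6 CPM, adjusted p 0.865), Gata3 (236 ± 63.2 against 85.6 ± 54.4, 0.301), Il4 (48.9 ± 9.89 against 8.78 ± 9.76, 0.954) and Il13 (0.865) did not pass. Nor did Cxcr5 (126 against 104 CPM), Pdcd1 (185 against 189) or Il21 (113 against 122; adjusted p 1), and Il5 had 0 counts in both.

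In the CXCR5hi gate, edgeR called 10 genes between TFH2 and TFH, 7 higher and 3 lower, and 675 had an unadjusted p under 0.05. The groups did not overlap in any of the 10, as in 17.03% of all genes tested. None of the 10 held with every library left out. Without TFH CXCR5hi replicate 2 all 10 calls were lost and edgeR called 0 genes, with an unadjusted p under 0.05 in 559. It was 6 without TFH replicate 1, 8 without TFH replicate 3, 21 without TFH2 replicate 1 (10 higher and 11 lower) and 16 without TFH2 replicate 2, and on all libraries DESeq2 called 77 (35 and 42). The highest adjusted p with a library left out was 0.435 for Klf2, 0.364 for Igkc, 0.237 for Hbb-bs and for Pik3r5, 0.414 for C1qc, 0.443 for Ifngr1, 0.298 for Psap, 0.659 for Chuk, 0.511 for Hist1h1e and 0.19 for Ddx3y. A fit on only these groups ended the calls of Klf2 (0.227), Psap and Chuk (both 0.218), Hist1h1e (0.666), and Ifngr1 and Pik3r5 (both 1), whose lowest values over alternatives were 2.02e-05 to 0.00718.

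The interferon response list was lower in TFH2 CXCR5hi cells (0 of 20 genes called, 0 over the list alone, median -1.32, camera adjusted p 4.91e-09) and the myeloid list higher (0 of 12, 2 over the list alone, median 1.77, 4.91e-09). Both held with an estimated correlation and with every library left out. The erythroid list was higher (1 of 5, 3 over the list alone, median 3.36, 8.87e-06, with an estimated correlation 0.0214), but not without TFH2 CXCR5hi replicate 2 (0.227) or TFH CXCR5hi replicate 2 (0.0536). The B cell list was higher (1 of 14, 2 over the list alone, median 1.88 [0.88], 0.000215, with an estimated correlation 0.0417) and was lost whichever library was left out (0.0541 to 0.77). The TH2 list did not pass in this gate (0 of 16, 1 over the list alone, median 0, 0.486). Median and mean differ in sign for the TFH list (-0.04 and 0.05, adjusted p 0.907), the naive list (-0.22 and 0.29, 0.752) and cholesterol synthesis (-0.15 and 0.25, 0.752).

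CXCR5hi cells (n = 5, TFH and TFH2) differed from CXCR5lo cells (n = 5) in TFH genes. Tox2 was 2.37 ± 0.36 log2 higher (886 ± 152 against 172 ± 70.1 CPM, adjusted p 0.000576). Pde3b, a phosphodiesterase, was 2.29 ± 0.43 higher, Smco4, a small membrane protein, 1.69 ± 0.23 and Cd52, a surface glycoprotein of lymphocytes, 0.93 ± 0.16 (adjusted p 0.000369, 1.47e-07 and 4.54e-05). Bcl6 was 2.13 ± 0.54 higher (200.3 ± 89.7 against 44 ± 22.7 CPM, adjusted p 0.0322). Its call was lost without any 1 of the 4 TFH2 libraries (0.0686 to 0.17), TFH CXCR5hi replicate 1 (0.0695), TFH CXCR5lo replicate 1 (0.0935) or 2 (0.0626), and without the 3 libraries of lowest depth (0.0561, range over alternatives 0.000329 to 0.0561). Cxcr5 is the gate and is no finding here (115 ± 23.4 against 27.1 ± 8.70 CPM). Pdcd1 (187 ± 27.9 against 41.8 ± 34.3 CPM, adjusted p 0.423), Il21 (118 ± 42.8 against 46.3 ± 27.3, 0.612) and Gata3 (160.5 ± 96.0 against 256.5 ± 159, 0.567) did not pass, nor did Il4 or Il13 (0.956 to 1). Il5 had 0 counts in the CXCR5hi libraries, so its test cannot decide (standard error 9010). TFH2 CXCR5lo replicate 1 held 0 Pdcd1 counts, though its gate is PD1+, while replicate 2 held 62.6 CPM.

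Lower in CXCR5hi cells were Rasgrp2, which activates integrins through Rap1 (log2 -3.05 ± 0.29, 68.6 ± 44.1 against 489 ± 206 CPM), and Anxa6, a membrane-binding annexin (-2.77 ± 0.27, 81.2 ± 14.6 against 568 ± 142 CPM; both adjusted p 1.15e-14). S1pr1 was lower by -2.60 ± 0.35, Klf2 by -1.92 ± 0.30 and Satb1 by -1.35 ± 0.23 (adjusted p 6.12e-08, 3.12e-06 and 3.75e-05). Vim, an intermediate filament, was lower by -2.66 ± 0.45, Esyt1, a lipid transfer protein, by -3.54 ± 0.59 and Sema4a, a semaphorin, by -4.38 ± 0.80 (adjusted p 0.00524, 0.0117 and 0.00232). Cytotoxic genes were lower too: Runx3 by -2.40 ± 0.36, Nkg7, a granule protein, by -7.09 ± 1.5 (2.76 ± 4.94 against 91.6 ± 72.0 CPM) and Ctsw, a granule protease, with 4 counts against 66.2 ± 64.8 CPM (adjusted p 1.35e-06, 0.0036 and 0.000327).

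Between CXCR5hi and CXCR5lo, edgeR called 58 genes, 16 higher and 42 lower. In 34 of them the groups did not overlap, as in 1.37% of all genes tested. Without TFH2 CXCR5lo replicate 1 the count was 140 and the balance turned (82 higher and 58 lower), and in a fit on only these groups it was near even (34 and 39). Of 23 called genes under the naming rule, 16 held with every library left out. The TFH list was higher (2 of 20 genes, 7 over the list alone, median 1.32, camera adjusted p 3.42e-10), and the TH1 and cytotoxic list (4 of 18 lower, 9 over the list alone, median -3.70 [-2.52], 7.47e-10) and the naive and recirculating list (3 of 19, 5 over the list alone, median -0.54, 1.84e-06) were lower. These 3 held with an estimated correlation and with every library left out. The inhibitory receptor list was higher (0 of 9, 2 over the list alone, median 1.85, 0.00422, with an estimated correlation 0.023). It was lost without TFH2 CXCR5lo replicate 1 (0.0907) or 2 (0.141), TFH2 CXCR5hi replicate 2 (0.267), TFH CXCR5hi replicate 2 (0.0722) or TFH CXCR5lo replicate 3 (0.0634). The myeloid list was higher (0 of 12, 0 over the list alone, median 0.94, 0.00418, with an estimated correlation 0.0247). It was lost without TFH2 CXCR5hi replicate 1 (0.0827) or 2 (0.118), TFH2 CXCR5lo replicate 1 (0.202), TFH CXCR5hi replicate 2 (0.0722) or TFH CXCR5lo replicate 2 (0.0575). Camera also called the cell cycle list (median -0.78, 0.0163) and the ribosomal protein list (median -0.28, 0.0163), which were lost with an estimated correlation (adjusted p 0.429 and 0.171). The TH2 list did not pass (median -0.71, 0.118).

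The difference between CXCR5 gates was itself compared between TFH2 (n = 4) and TFH (n = 6) cells. Fam3c, a secreted factor, stood at 67.4 ± 35.9 CPM in TFH2 CXCR5hi cells and at 0 counts in TFH2 CXCR5lo cells, against 58.6 ± 59.2 and 64.5 ± 11.5 CPM in TFH cells (fitted log2 difference of differences 10.8, adjusted p 0.000327). For this interaction edgeR called 2 genes, both higher, and 787 had an unadjusted p under 0.05. The other is Smad5, a BMP signal carrier, at 27.1 and 0 CPM in TFH2 and 20.9 and 52.3 CPM in TFH cells (10.67, adjusted p 0.0331). Smad5 lost its call without TFH2 CXCR5hi replicate 1, either TFH2 CXCR5lo library, TFH CXCR5hi replicate 3 or TFH CXCR5lo replicate 3 (up to 0.304). It was lost too in a fit on only these groups (0.347) and without the 3 libraries of lowest depth (0.151, range over alternatives 0.000718 to 0.347). The count was 43 without TFH2 CXCR5lo replicate 1 (42 higher), 12 and 7 without TFH2 CXCR5hi replicates 1 and 2 (9 and 5 lower), 4 without TFH CXCR5hi replicate 1, and 1 without TFH CXCR5hi replicate 3 or TFH CXCR5lo replicate 3. Bcl6 (2.14 ± 1.04, adjusted p 0.908), Cxcr5 (-0.39 ± 1.47), Pdcd1 (0.72 ± 1.45), Gata3 (-0.07 ± 0.59), Il21 (0.11 ± 1.31), Il4 (1.20 ± 3.07) and Il13 (-1.59 ± 2.87) did not pass (adjusted p 1 from Cxcr5 on). Il5 had 0 counts in all but the TFH2 CXCR5lo libraries here, so its test cannot decide (standard error 17727).

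By list, the mean log2 score of TH2 genes was higher in TFH2 than in TFH cells by 0.65, 1.68 and 2.54 from the CXCR5hi to the CXCR5lo gate. The interaction, hi against lo, had a median of -2.07 over 16 genes (0 called, 0 over the list alone, camera adjusted p 0.000386, with an estimated correlation 0.0217). It was lost without TFH2 CXCR5hi replicate 1 (0.0861), TFH2 CXCR5lo replicate 1 (0.156) or 2 (0.0803) or TFH CXCR5hi replicate 3 (0.0534). The naive and recirculating list went the other way (median 1.92, 0 of 19 called, 3 over the list alone, 0.000522, with an estimated correlation 0.0217) and was lost without TFH2 CXCR5hi replicate 1 (0.0582) or 2 (0.0893) or TFH2 CXCR5lo replicate 1 (0.156). The same score differences were -1.57, -2.27 and -2.31 for the interferon list, 2.47, 1.71 and 1.56 for the myeloid list, 1.91, 1.26 and 1.23 for the B cell list and 3.5, 3.07 and 3.17 for the erythroid list, and none of these 4 passed. Camera called the TH1 and cytotoxic list (median -0.81, 0.00443) and the cell cycle list (median -1.4, 0.00106), which were lost with an estimated correlation (adjusted p 0.163 and 0.462).

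**Figure D3:**
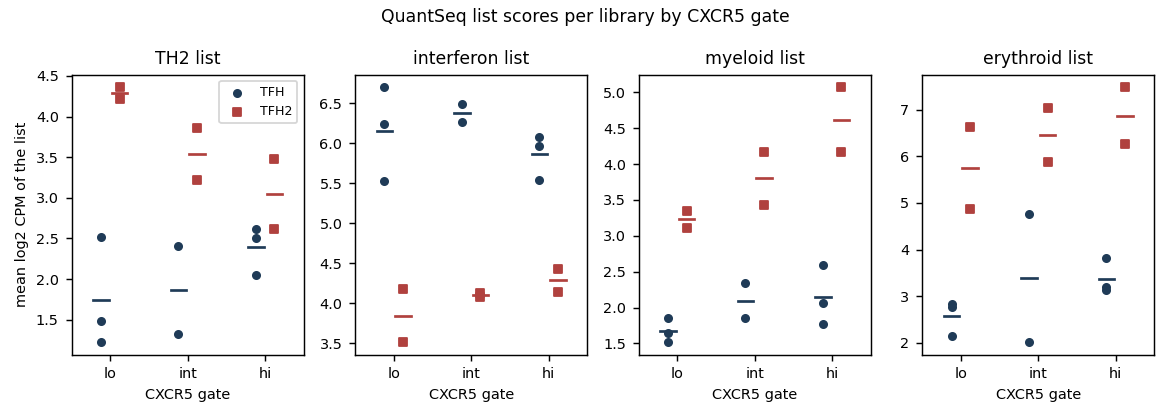
Mean log2 CPM of the TH2, interferon, myeloid and erythroid lists in each library by CXCR5 gate. Circles are TFH libraries, squares TFH2 libraries and lines means.

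Bcl6KO cells (n = 2) and TH2 cells (n = 4) shared the CD4+hCD2+ gate. The Bcl6KO genotype label names no IL-4BacTg allele while that of TH2 does, so it is not known whether the gate took the same kind of cell from both. Ipcef1, a regulator of ARF6 exchange factors, was higher in Bcl6KO cells (169 ± 54.3 against 27.9 ± 9.54 CPM, log2 2.59 ± 0.43, adjusted p 0.000307). S100a4, a calcium-binding protein of motile effector cells, was lower (19.6 ± 9.67 against 101 ± 22.6 CPM, log2 -2.35 ± 0.47, 0.00841). Bcl6 (1.55 ± 0.70, adjusted p 0.847) and Gata3 (283 against 263 CPM, 0.11 ± 0.39) did not pass, Il13 stood at 13.7 ± 19.4 against 1.4 ± 1.66 CPM, and Cxcr5, Il21 and Il5 had 0 counts in both. Il4 had 0 counts against 3.42 ± 6.84 CPM and Pdcd1 0 against 3 counts (adjusted p 0.847 and 0.908). The edgeR test called 3 genes, and the groups did not overlap in any, as in 9.61% of all genes tested. In all, 837 genes had an unadjusted p under 0.05. S100a4 lost its call without Bcl6KO replicate 2 (0.439), in a fit on only these groups (0.846) and without the 3 libraries of lowest depth (0.206, range over alternatives 2.21e-05 to 0.846). Ipcef1 lost it in a fit on only these groups (0.416, range over alternatives 6.29e-08 to 0.416). The count was 8, 7, 9 and 20 without TH2 replicates 1 to 4, 56 without Bcl6KO replicate 1 (50 lower) and 21 without replicate 2 (19 lower). It was 63 against the TH2 libraries titled Sample 9 and 10 and 50 against Sample 25 and 28, and DESeq2 called 124 (107 lower). Of the lists, camera called only the cell cycle list (0 of 27 genes, 0 over the list alone, median -2.11, 0.0353), which was lost with an estimated correlation (adjusted p 0.593).

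Il4KO cells (n = 2) were compared with TH2 cells (n = 4), though the gates differ. Klf4, a factor of quiescence, had 0 counts in Il4KO cells against 10.8 ± 8.00 CPM (at least 11-fold lower, adjusted p 4.79e-06), and Itpr1, a calcium channel of the endoplasmic reticulum, 1 count against 47.1 CPM (8.55e-06). Hspa5, a chaperone of secretory cells, was lower by log2 -1.24 ± 0.26 (157 ± 20.0 against 371 ± 59.1 CPM, 0.00994), Nlrc5, which drives MHC class I, by -5.36 ± 0.98 (0.00141), Pttg1, a securin of dividing cells, by -2.52 ± 0.54 (0.0174) and Nfkbia by -0.86 ± 0.20 (0.0372). Myb stood at 0 counts against 7.93 CPM (at least 8.09-fold lower, 0.0176). The 1 gene called higher was Il21, with 33 counts in 1 library and 0 in TH2 (0.00738). Gata3 (160 against 263 CPM), Bcl6 (12.3 against 5.42 CPM) and Il13 (0 counts against 1.4 CPM) did not pass (adjusted p 0.924), nor did Il4 (3 counts against 3.42 CPM) or Pdcd1 (2 against 3 counts; adjusted p 1). Cxcr5 and Il5 had 0 counts in both.

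Between Il4KO and TH2, edgeR called 10 genes, 1 higher and 9 lower, and 768 had an unadjusted p under 0.05. In 7 calls the groups did not overlap, as in 9.96% of all genes tested. Klf4 and Itpr1 alone held with every library left out. Without Il4KO replicate 1 the adjusted p was 1 for Il21, 0.89 for Nfkbia, 0.217 for Hspa5 and 0.102 for Nlrc5. Nfkbia was also lost without TH2 replicate 1, and Myb and Pttg1 without either Il4KO library (up to 0.217 and 0.414). In a fit on only these groups edgeR called 0 genes, and the 7 lower genes named here stood at 0.679 to 1, against lowest values over alternatives of 9.5e-11 to 0.000905. Against TH2 subsets, Pttg1 was lost with the libraries titled Sample 9 and 10 (0.295) and Il21 with Sample 25 and 28 (0.0521, range over alternatives 0.000459 to 0.0521). The count was 23 without Il4KO replicate 1, 27 without Il4KO replicate 2, 23 without TH2 replicate 3 and 31 without TH2 replicate 4, 74 against Sample 9 and 10 and 33 against Sample 25 and 28, and DESeq2 called 91. The immediate early list was lower (1 of 19, 3 over the list alone, median -1.08 [-1.03], camera adjusted p 0.00292, with an estimated correlation 0.0332), but not without TH2 replicate 2 (0.0958), TH2 replicate 3 (0.104) or Il4KO replicate 1 (0.538). The cell cycle list (median -3.15 [-2.74], 2.47e-06) and the regulatory T cell list (median -1.05 [-0.71], 0.0328) were lost with an estimated correlation (adjusted p 0.5 and 0.233).

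Bcl6KO and Il4KO cells (n = 2 each) were also compared directly. Klf4 was at 13.1 ± 1.6 CPM in Bcl6KO cells and 0 in Il4KO cells (at least 13.3-fold, adjusted p 4.7e-06), Nlrc5 was 6.47 ± 1.05 log2 higher (108 against 1.21 CPM, 0.000108) and Itpr1 stood at 29.9 CPM against 1 count (0.000122). Hspa5 was 1.48 ± 0.29 higher (0.00282), Ipcef1 2.60 ± 0.55 (0.0178) and Pttg1 2.57 ± 0.58 (0.0341), and Klf2 was lower by -2.06 ± 0.46 (81 against 338 CPM, 0.0341). Bcl6 (16.2 against 12.3 CPM, adjusted p 1), Gata3 (283 against 160, 0.917), Il13 (13.7 against 0, 0.917), Il21 (0 against 5.1, 0.181), Il4 (0 against 3 counts, 0.958) and Pdcd1 (0 against 2 counts, 1) did not pass, and Cxcr5 and Il5 had 0 counts in both. In this comparison edgeR called 8 genes, 6 higher and 2 lower, all with groups that do not overlap, as in 26.11% of all genes tested, and 525 had an unadjusted p under 0.05. Klf4 and Nlrc5 held with every library left out. Itpr1 and Hspa5 were lost without Il4KO replicate 1 (0.0525 and 0.0799), Ipcef1 without that library (0.63) or Bcl6KO replicate 1 (0.08), Klf2 without either Il4KO library or Bcl6KO replicate 1 (0.105 to 0.54), and Pttg1 without either Il4KO library or Bcl6KO replicate 2 (0.1 to 0.569). In a fit on only these groups edgeR called 0 genes and these 7 stood at 1, against lowest values over alternatives of 7.21e-09 to 0.000819. Pttg1 was also lost without the 3 libraries of lowest depth (0.319), and DESeq2 over all groups called 77 (38 higher and 39 lower). The count was 13 and 21 without Il4KO replicates 1 and 2, 54 without Bcl6KO replicate 1 (16 higher and 38 lower) and 22 without replicate 2 (9 and 13). No list passed (adjusted p 0.168 to 0.968).

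In RNA-seq, TH2 cells (n = 2) carried cytokines and receptors of type 2 immunity that naive cells (n = 2) lacked. Il4 was 7.74 ± 0.19 log2 higher (23.7 ± 0.705 against 0.109 CPM), Il13 9.32 ± 0.35 and Gata3 3.04 ± 0.11 (699.5 ± 107 against 85 ± 3.2 CPM; adjusted p 4.74e-11, 3.04e-07 and 8.52e-10). Il5 stood at 3.58 CPM against 1 count (1.55e-07). Il1rl1, the IL-33 receptor, was 9.51 ± 0.13 higher, Il10, a suppressive cytokine, 9.59 ± 0.19, and the homing receptors Ccr8 and Ccr4 6.94 ± 0.12 and 6.80 ± 0.11 (adjusted p at most 1.17e-11). Gzmb, a cytotoxic protease, was 13.77 ± 0.22 higher (2604 against 0.187 CPM), Cxcr6 8.30 ± 0.15 and Mki67, a proliferation marker, 7.44 ± 0.12 (1204 against 6.92 CPM; adjusted p for Mki67 5.74e-12). Cysltr1, a leukotriene receptor, stood at 126 CPM against 0 (at least 1390-fold) and Hes1, a Notch target, at 53.4 against 0 (at least 589-fold).

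Lower in TH2 than in naive cells were Actn1 (log2 -5.91 ± 0.10, adjusted p 6.19e-12), Tcf7, a factor of naive and TFH cells (-3.87 ± 0.09, 3.29e-11), and Bcl6 (7.34 against 28.5 CPM, -1.96 ± 0.09, 6.42e-09). Cxcr5 had 0 counts against 3.95 CPM (at least 30.3-fold lower, 4.78e-08). Pdcd1 was 0.58 ± 0.11 higher (0.000666), a call lost in the test against 2-fold (1) and with the library labelled TH2 added (0.158, range over alternatives 0.00016 to 1), and Il21 (0.177 against 0.21 CPM) did not pass (0.712). The edgeR test called 11191 genes, 5764 higher and 5427 lower, 5561 of them at least 2-fold, and 90 of 91 called genes under the naming rule held with every library left out. With the library labelled TH2 of the IL-4BacTg x OTII mice in the TH2 group, the count was 5352, and Tcf7 (0.374), Cxcr5 (0.437) and Bcl6 (0.762) lost their calls. Over alternatives Bcl6 ranged from 1.22e-80 to 0.762 and Cxcr5 from 7.09e-63 to 0.437. Cell cycle genes (27 of 27 higher, 27 over the list alone, median 5.67, camera adjusted p 2.05e-12), TH2 genes (19 of 20, 19, median 6.27, 4.53e-09), glycolysis and hypoxia genes (14 of 15, 14, with 1 lower, median 1.69, 6.18e-06), respiratory chain genes (17 of 17, 17, median 0.65, 0.000202), cholesterol synthesis genes (13 of 14, 13, median 0.83, 0.000223) and regulatory T cell genes (11 of 14 higher and 3 lower, 11 and 3, median 2.94, 0.00532) were higher. With an estimated correlation these 6 and the 4 lists that follow were lost (adjusted p 0.18 to 0.452). Naive genes (16 of 19 lower and 1 higher, 16 and 1, median -2.36, 2.13e-06), interferon genes (15 of 20 lower and 4 higher, 15 and 4, median -1.72, 0.000505), TFH genes (11 of 20 lower and 6 higher, 11 and 6, median -1.2, 0.0272) and immediate early genes (13 of 20 lower and 4 higher, 14 and 4, median -0.65, 0.0287) were lower.

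TFH CXCR5hi cells in RNA-seq (n = 2) carried the TFH program against naive cells (n = 2). Cxcr5 was 6.80 ± 0.10 log2 higher (440 ± 5.64 against 3.95 CPM), Bcl6 3.80 ± 0.08 (399 against 28.5 CPM), Pdcd1 6.49 ± 0.09 (374 against 4.16 CPM) and Il21 9.81 ± 0.14 (194 against 0.21 CPM; adjusted p for Il21 5.58e-12). Il4 was 8.87 ± 0.18 higher (51.8 against 0.109 CPM, 1.79e-11). Gata3 was 1.18 ± 0.11 higher, which did not pass the test against 2-fold (0.0917, range over alternatives 2.64e-34 to 0.0917). Il13 (0.324 against 0.113 CPM, adjusted p 0.236) and Il5 (1 count in each, 0.853) did not pass. Sostdc1, a Wnt and BMP antagonist, was 10.14 ± 0.17 higher, Cebpa 9.93 ± 0.21, Angptl2 8.19 ± 0.15 and the inhibitory receptor Tigit 7.82 ± 0.11 (adjusted p at most 8.47e-11). Nr4a2 and Nr4a3 were 5.29 ± 0.10 and 4.62 ± 0.09 higher, and Isg15, an interferon-induced modifier, 2.63 ± 0.08 (4.35e-10). Igfbp4, a growth factor binder of naive cells, was lower by -9.44 ± 0.18, Il7r, the survival receptor, by -5.23 ± 0.13 and Foxp3, the regulatory T cell factor, by -4.09 ± 0.12 (3.51 against 60.3 CPM; adjusted p at most 2.06e-10).

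Between RNA-seq TFH and naive cells, edgeR called 9736 genes, 5040 higher and 4696 lower, 4176 of them at least 2-fold, and 82 of 83 called genes under the naming rule held with every library left out. TFH genes were higher (20 of 20, 20 over the list alone, median 2.91, camera adjusted p 3.99e-11), with immediate early (16 of 20 and 3 lower, 16 and 3, median 1.35, 0.000234), inhibitory receptor (8 of 11 and 2 lower, 8 and 2, median 3.72, 0.00149), cell cycle (16 of 27 and 2 lower, 16 and 2, median 0.5, 0.00149), interferon (13 of 20 and 3 lower, 13 and 3, median 0.73, 0.00524), glycolysis (12 of 15 and 2 lower, 12 and 2, median 0.62, 0.00551), respiratory chain (8 of 17, 8, median 0.2, 0.0272), TH17 (5 of 8, 6, median 3.37, 0.0272) and TH2 genes (10 of 20 and 3 lower, 10 and 3, median 1.33 [1.05], 0.0278). With an estimated correlation these 9 and the 2 lists that follow were lost (adjusted p 0.217 to 0.586). Naive (18 of 19 lower and 1 higher, 18 and 1, median -2.34, 1.76e-08) and ribosomal protein genes (17 of 18, 17, median -0.97, 1.56e-06) were lower.

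Set against TH2 cells in RNA-seq (n = 2 each), TFH cells had higher Cxcr5 (440 ± 5.64 CPM against 0, at least 3370-fold), Il21 (log2 10.08 ± 0.15), Tox, a nuclear factor of TFH and exhausted cells (6.87 ± 0.10), Pdcd1 (5.91 ± 0.09) and Bcl6 (5.76 ± 0.09; adjusted p at most 6.67e-12). Nr4a3 was 9.54 ± 0.14 higher, Ikzf2, the Helios factor, 7.64 ± 0.12, and Isg15 4.74 ± 0.10 (adjusted p at most 1.88e-11). Il4 was higher in TFH cells (51.8 against 23.7 CPM, 1.13 ± 0.09, adjusted p 5.61e-07), a call lost with summed transcripts (0.225) and in the test against 2-fold (0.113, range over alternatives 3.77e-34 to 0.93). Of the type 2 genes, Il1rl1 was lower by -11.23 ± 0.16, Il13 by -7.86 ± 0.33 (0.324 against 71.1 CPM), Ccr8 by -6.66 ± 0.12, Il10 by -6.01 ± 0.14, Il4ra by -5.10 ± 0.10 and Gata3 by -1.86 ± 0.11 (193 against 699.5 CPM, 3.91e-08). Il5 stood at 1 count against 3.58 CPM. Pparg, a lipid-sensing TH2 factor, had 0 counts in TFH cells against 43.3 CPM (at least 327-fold lower, 2.65e-10). Gzmb was lower by -13.53 ± 0.23, Entpd1, an ATP-degrading ectoenzyme, by -8.49 ± 0.14, Il2ra, the IL-2 receptor, by -7.22 ± 0.13 and Mki67 by -5.45 ± 0.11 (adjusted p at most 1.02e-11).

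Between RNA-seq TFH and TH2 cells, edgeR called 10510 genes, 5243 higher and 5267 lower, 5050 of them at least 2-fold, and all 89 called genes under the naming rule held with every library left out. With the library labelled TH2 of the IL-4BacTg x OTII mice in the TH2 group the count was 4201. Calls lost were Cxcr5 (0.398), Il21 (0.456), Tox (0.152), Pdcd1 (0.181), Bcl6 (0.128), Nr4a3 (0.213), Ikzf2 (0.19), Isg15 (0.305), Il4 (0.93), Gata3 (0.078), Il10 (0.0558) and Il4ra (0.0976), whose lowest values over alternatives were at most 3.77e-34. TFH genes were higher (19 of 20 and 1 lower, 19 and 1 over the list alone, median 5.83, camera adjusted p 1.78e-10), with interferon (18 of 20 and 1 lower, 18 and 1, median 2.56, 3.62e-07), immediate early (18 of 20 and 1 lower, 18 and 1, median 1.71, 1.1e-06), inhibitory receptor (8 of 11 and 2 lower, 8 and 2, median 3.23, 0.0076) and B cell genes (11 of 19 and 3 lower, 11 and 3, median 3.16 [0.74], 0.0212). With an estimated correlation these 5 and the 6 lists that follow were lost (adjusted p 0.167 to 0.543). Cell cycle (26 of 27 lower and 1 higher, 26 and 1, median -4.91, 1.17e-11), ribosomal protein (17 of 18, 17, median -0.74, 7.49e-05), glycolysis (13 of 15 and 1 higher, 13 and 1, median -1.23, 0.00013), TH2 (15 of 20 and 4 higher, 15 and 4, median -3.65, 0.000486), respiratory chain (11 of 17 and 1 higher, 12 and 1, median -0.42, 0.0165) and cholesterol genes (8 of 14 and 2 higher, 8 and 2, median -0.68, 0.0167) were lower. Over all RNA-seq comparisons, 32 list calls by camera thus became 0, while in QuantSeq 35 of 46 held. The RNA-seq fit has 3 residual degrees of freedom against 13 in QuantSeq, so the test with an estimated correlation has little power there. Its losses do not show that the RNA-seq lists are less sound, and fry called 47 of 57 RNA-seq lists. Igkc itself stood at 6.28 CPM against 1 count, a call lost with the library labelled TH2 added (0.423). The mitochondrially encoded genes had 0 counts in these 6 libraries, and the CD8 and NK cell list passed in no comparison.

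**Figure D4:**
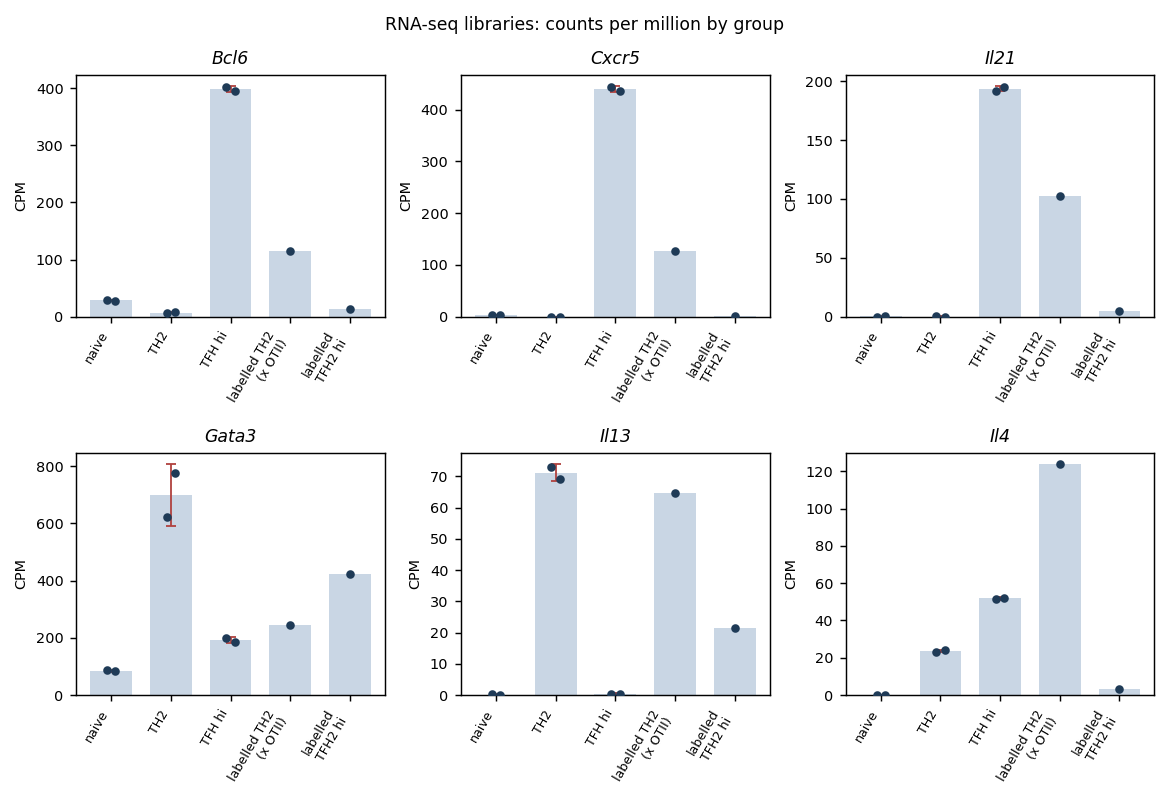
Expression of Bcl6, Cxcr5, Il21, Gata3, Il13 and Il4 in the 5 RNA-seq groups, named by their labels. Bars are means, points are libraries and red lines are standard deviations.

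Of the RNA-seq libraries of IL-4BacTg x OTII mice (n = 1 each), the library labelled TFH2 CXCR5hi lacked the TFH genes its label implies and the library labelled TH2 carried them beside TH2 genes. Neither was tested as a group. The library labelled TFH2 CXCR5hi held 1.09 CPM of Cxcr5 (14 counts), 12.8 of Bcl6, 5.83 of Pdcd1, 5.06 of Il21, 3.42 of Il4, 21.4 of Il13, 4.51 of Il5 and 424 of Gata3. The library labelled TH2 held 128 CPM of Cxcr5, 114 of Bcl6, 131 of Pdcd1, 102 of Il21, 124 of Il4, 64.6 of Il13, 22.9 of Il5 and 243 of Gata3. Ddx3y was at 111 CPM in the library labelled TFH2 CXCR5hi and 7.49 in the library labelled TH2, and Xist at 0.934 and 697 CPM. In the library labelled TFH2 CXCR5hi, 262 genes were at least 4-fold higher and 527 at least 4-fold lower. Of the lists, its TFH genes had a median log2 difference of -3.49, immediate early genes -5.04, inhibitory receptor genes -2.08, interferon genes -1.17, B cell genes -3.86, myeloid genes -2.47 and cell cycle genes -0.77, each below all 10000 random lists. TH1 and cytotoxic genes (1.68), naive genes (0.71) and cholesterol genes (0.99) were above all of them. The TH2 list (0.49) stood at percentile 99.93. Principal component 1 of RNA-seq (61.9% of the variance) parted these 2 libraries from the other 6, which hold no mitochondrial counts. Only the alternative that adds the library labelled TH2 to the TH2 group sets 1 of them against those 6.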

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

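Chosen only after results were seen were the tests of a poor sort, of macrophage, B cell or erythroid carry-over and of the Bcl6 allele, and the interval rule applied to the preparation share. The other tests in this part were written before.

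The 4 TH2 libraries of QuantSeq were the only group large enough to ask whether a single library lies far from its replicates. In 33 measures a Dixon test singled out 4 values, where 1.7 are expected by chance at 5%. TH2 replicate 2 had a TFH list score of 3.25 (others 2.42 to 2.53), replicate 3 a naive list score of 6.42 (others 5.92 to 5.96) and an Il4 level of 13.7 CPM (others 0), and replicate 4 a glycolysis list score of 5.01 (others 5.73 to 5.8).

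The difference between CXCR5hi and CXCR5lo cells was not the same in TFH2 and TFH cells, by a test of the interaction. It was found for Fam3c (log2 10.8, adjusted p 0.000327), Smad5 (10.67, 0.0331), the TH2 list (median -2.07) and the naive and recirculating list (median 1.92; both 0.0217 with an estimated correlation). Fam3c and Smad5 had 0 counts in both TFH2 CXCR5lo libraries, so their values are fitted and unbounded. Only Fam3c held with every library left out.

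The RNA-seq library labelled TH2 of the IL-4BacTg x OTII mice carries TFH transcripts and the library labelled TFH2 CXCR5hi lacks them. A poor sort of the library labelled TFH2 alone is argued against by the 128 CPM of Cxcr5 in the library labelled TH2. Of 393 genes called between TFH2 CXCR5hi and TH2 in QuantSeq, 85.8% (337) differ the opposite way between these 2 libraries, which fits an exchange of their labels. Other values go with the labels as given: cell cycle genes are lower in the library labelled TFH2 (median -0.77, 0 of 27 higher), as in RNA-seq TFH against TH2 cells (-4.91), and that library is male (Ddx3y 111 CPM), as all 6 QuantSeq TFH2 libraries are. Whether tubes, cells or names were exchanged was not tested, and no biological explanation was tested.

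In QuantSeq the TH2 list is higher and the interferon list lower in TFH2 than in TFH cells. Basophils or mast cells cannot be excluded, although the gate is CD4+. Their 9 markers sum to 58 ± 25.8 CPM in TFH2 and 24.8 ± 19.8 in TFH libraries. This difference is 38.6% of that in Il4 plus Il13 (96.2 ± 22.7 against 10.2 ± 5.76 CPM). The most abundant are Mcpt8 (17.4 against 0.107 CPM) and Hdc (15.7 against 8.1), and 4 of the 9 reach 5 CPM in TFH2, 2 in TFH and 1 in TH2 cells. Macrophage, B cell or erythroid carry-over, which the same gate would remove, as the source of the TH2 difference is argued against by the interaction of the TH2 list alone (0.0217 with an estimated correlation), but 4 of 10 fits with a library left out lose it (0.0534 to 0.156), so it stays open. A preparation difference stays open as well, since the share of calls that also part the TH2 libraries titled Sample 9 and 10 from Sample 25 and 28 the same way is 55.9% of 93 (95% interval 45 to 66.2) against a bound of 60. In size, these genes moved by a median of 0.04 log2 towards TFH2 between the TH2 libraries, against 1.27 between TFH2 and TFH. The genes were chosen by their calls in the second contrast, so its size is large by selection. The spread of the first median was not tested, and these sizes cannot decide. Component 2 goes with such a difference. Sample 9 and 10 (32.6 and 26.3) lie with TFH2, and Sample 25 and 28 (-9.9 and -16.63) with TFH libraries.

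That interval takes genes as independent, which they are not, and it was added after the share was known. The share is 56.5% without sex-linked genes, 59.5% with at least 10 counts and 60.5% without ties. In Sample 9 and 10 against Sample 25 and 28 the TH2 list had a median of 0.29 (9 of 16 genes higher) and the interferon list 0.41 (11 of 20). The first 2 are female and the others male, while TFH2 libraries are male and TFH libraries female, so this contrast mixes preparation with donor sex, in the reverse order. Genotype, and donor sex with it, could also part TFH2 from TFH cells. Genotype was not tested apart from sex, and sex at 1 genotype only in these TH2 libraries.

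Few genes are called between Bcl6KO and TH2 cells with all libraries (3), but 63 against the TH2 libraries titled Sample 9 and 10, 50 against Sample 25 and 28, 56 without Bcl6KO replicate 1 and 124 with DESeq2. Replicate spread (6% of 200 simulated 4-fold changes recovered) cannot decide, as TFH2 CXCR5hi against TH2, also n = 2 and 4, had 423 calls. Whether the Bcl6 allele was deleted cannot be told from the 21 and 54 Bcl6 counts in Bcl6KO libraries, of unknown position in the gene. A small role of Bcl6 in cells of this gate could give the same result and was not tested.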

How the results depend on the processing

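Most values kept their direction and side of the threshold. Of named-gene values under all alternatives, 9789 kept both, 453 lost a call and 102 gained 1. Sign changed in 278 without and 15 with a call. Chosen after the data were seen were the fit without the 3 QuantSeq libraries of lowest depth and, for RNA-seq, DESeq2, RLE factors, summed transcripts and the test against 2-fold. No paired analysis was possible because the labels give no replicate numbers and do not say which libraries share mice, so replicates are numbered here only by their order in the series and all fits take libraries as independent. In QuantSeq a library has 1.83 to 4.44 M counts, and 6 to 36% of simulated 4-fold changes were recovered.

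RLE factors left all QuantSeq counts close to their values (TFH2 against TFH 90, other counts 2 to 498), and no called list changed sign. DESeq2 called 279 genes for TFH2 against TFH, 77 in the CXCR5hi gate, 827 for TFH2 CXCR5hi against TH2, 977 for TFH CXCR5hi against TH2, 124 for Bcl6KO and 91 for Il4KO against TH2, 77 for Bcl6KO against Il4KO, 222 between CXCR5 gates and 35 for the interaction. The cause was not tested. At an adjusted p under 0.01, which is stricter by construction, the first 4 were 51, 0, 243 and 294, Il4KO 5, Bcl6KO against Il4KO 4 and the interaction 1. Without a filter the counts were 142 for TFH2 against TFH, 25 in the CXCR5hi gate, 17 for Bcl6KO, 38 for Il4KO, 20 between them and 4 for the interaction, and the cause was not tested.

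A fit on only the groups compared, with fewer libraries for the spread, called 1 gene for Bcl6KO, 0 for Il4KO and 0 between them, but 139 for TFH2 against TFH, 73 between CXCR5 gates and 14 in the CXCR5hi gate (4 of them shared with the 10). Against the TH2 libraries titled Sample 9 and 10 the counts were 63 for Bcl6KO and 74 for Il4KO, and against Sample 25 and 28 they were 50 and 33. With Sample 25 and 28, Top2a reversed between TFH CXCR5hi and TH2 to log2 2.03. Without the 3 libraries of lowest depth the counts were 35 for TFH2 against TFH in the CXCR5hi gate, 34 for Bcl6KO, 63 for Il4KO and 29 between them. In these cases the cause was not tested.

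With 1 library left out, the counts ran from 80 (TFH CXCR5lo replicate 2) to 214 (TFH2 CXCR5lo replicate 1) for TFH2 against TFH, 0 (TFH replicate 2) to 21 (TFH2 replicate 1) in the CXCR5hi gate, 307 (TFH2 CXCR5hi replicate 2) to 411 (TH2 replicate 3) for TFH2 CXCR5hi against TH2, and 336 (TFH CXCR5hi replicate 2) to 463 (TH2 replicate 1) for TFH CXCR5hi against TH2. They ran from 7 (TH2 replicate 2) to 56 (Bcl6KO replicate 1) for Bcl6KO, 10 (TH2 replicate 1) to 31 (TH2 replicate 4) for Il4KO, 13 (Il4KO replicate 1) to 54 (Bcl6KO replicate 1) between them, 51 (TFH CXCR5lo replicate 2) to 140 (TFH2 CXCR5lo replicate 1) between gates, and 1 (TFH CXCR5hi or CXCR5lo replicate 3) to 43 (TFH2 CXCR5lo replicate 1) for the interaction. In RNA-seq they ran from 9609 to 11339 (TH2 against naive), 7739 to 8059 (TFH against naive) and 8779 to 10855 (TFH against TH2). The cause was not tested.

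In RNA-seq, DESeq2 (9230, 7622 and 8572), limma, summed transcripts and the 6 replicated libraries alone kept the 3 counts near their values. The test against 2-fold, stricter by construction, called 4033, 2610 and 3587. With the library labelled TH2 of the IL-4BacTg x OTII mice in the TH2 group the counts were 5352 against naive and 4201 for TFH against TH2. Against naive, log2 ratios then reversed for Nr4a3 (0.61), Igkc (5.78), Csf1r (0.36), Klrb1c (5.56), Hbb-bs (2.67), Hbb-bt (2.76), Bcl6 (0.59) and Cxcr5 (3.43), and for TFH against TH2 they reversed for Cd74 (-3.78), Igkc (-3.78), Mpeg1 (-2.44), Hbb-bs (-1.63), Hbb-bt (-1.67) and Il4 (-0.14). The cause was not tested, and that library also differs from the other 6 in its mitochondrial counts (4.38% against 0). Of 78 list calls by camera, 35 held with an estimated correlation, all of them in QuantSeq, and fry called 97. The RNA-seq fit has 3 residual degrees of freedom, which leaves the estimated correlation little power. Of the 35 QuantSeq list calls, 25 held with every library left out.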

Other observations

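The tests in this part were written before the results were seen.

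Most genes called between TFH CXCR5hi and TH2 cells in QuantSeq differ in the same direction in RNA-seq. Of 475 genes called in QuantSeq and tested in RNA-seq, 88.8% (422) had the same sign there, where 49.6% is expected from the numbers higher and lower in each. Over all 11916 genes in both, called or not, it was 58.8%. Of 409 genes called in both, 93.2% had the same sign, with 241 higher in both (100.8 expected from independent lists) and 140 lower in both (63.1 expected). Most QuantSeq calls thus kept direction in RNA-seq, but 28 called in both did not. The TH2 list, lower in RNA-seq TFH cells, did not pass in QuantSeq. RNA-seq TH2 cells come from IL-4BacTg and QuantSeq TH2 cells from IL-4BacTg x OTII mice. In both assays TH2 cells carry IL-4BacTg and the CD4+hCD2+ gate, while TFH cells come from OTII mice and the CXCR5hi PD1+ gate. Cell type thus cannot be told apart from transgene and gate.

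Other splits of the libraries into groups of the same sizes asked how many calls arise without the real groups, in fits on the libraries compared. For TFH2 against TFH, 1 of 100 splits drawn from 600, the real one, reached 139 calls, and the highest other had 18. For TFH CXCR5hi against TH2 it was 1 of 35 (415 calls, highest other 1), and between CXCR5 gates 1 of 60 (73 calls, highest other 23). An origin of these counts in a random grouping is thus argued against in all 3 where libraries are independent. The labels do not say whether the CXCR5 gates share mice, which leaves this open for the first and the last.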
